A study of Drosophila melanogaster with 72 samples.

How the data were processed

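The series covered the mRNA modification N6-methyladenosine (m6A) and folic acid in Drosophila melanogaster and mouse. It was measured by MeRIP-seq, in which fragmented mRNA is immunoprecipitated with an antibody against m6A. Per the labels' protocols, about 1.5 µg of polyadenylated RNA was cut into fragments of about 100 nt, a part was kept as input, the rest went into the immunoprecipitation, and strand-specific libraries were read as paired ends of 150 nt. The 72 samples were 36 input libraries and 36 immunoprecipitated libraries from 12 conditions of 3 replicates. Of these, 10 conditions were compared, and 1 further experiment, 1 gene and 1 gene region are not reported here. S2 cells, a line derived from Drosophila embryos, were grown at 28 °C with 10% serum. The flies were of the w1118 strain and were reared at 25 °C. The mice were C57BL/6J, 3 weeks old at the start, and 0.1 mL per day at 500 µg/kg/day of folic acid was given by gavage for 14 days before the brain was taken. What the control mice received, the folate dose of the cells and flies, the meaning of the labels GF and LP, and the tissue and sex of the flies are not given in the sources used here.

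For the input libraries, the authors deposited count tables of whole-number read counts per gene, not normalised, and 3 were used here, for the S2 folate experiment, the mouse brains and the flies. Per the submitters' processing notes, the tools named were Trim Galore 0.6.6, SAMtools 1.3.1, featureCounts from Subread 2.0.1, DESeq2 1.36.0, HOMER 3.12, ChIPseeker 1.32.0 and deepTools 3.5.1, with the builds dm6 and mm39 and no role or order. Per the file headers, the count tables have the columns that featureCounts writes. For the immunoprecipitated libraries, the authors deposited 1 peak list per library with a score for each peak, and replicates were not pooled. The meaning of the score, the peak caller, the aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the Hsp70, Lys, PGRP-SC1, Att, Mst98C and cuticle protein genes, can therefore be split between them, and the values of such genes are uncertain. No counts of the immunoprecipitated libraries were used here, so the change of immunoprecipitated over input signal per gene that had been planned was not run.

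Each fly table held 17137 genes, of which 16293 matched a symbol of the reference table, and the mouse table held 50554 genes. In the mouse table, 18 lines with a coordinate cell broken across lines were left out, which cost the 5 genes Huwe1, Mycbp2, Neb, Syne1 and Ttn. Every row named a gene, and 0 value columns were left without a sample. Total counts per input library were 3774003 to 10743276 in the S2 folate experiment, 19312950 to 32571038 in mouse brain and 4344965 to 23665385 in flies. Replicates of a group correlated at 0.970 to 0.995, 0.866 to 0.993 and 0.840 to 0.990 across genes on the log2 scale in these 3 tables. Between replicates the chi-square per gene was at least 3.68, so 0 pairs of libraries were counted as 1. The biological coefficient of variation was 0.111, 0.283 and 0.256 in the same order, so folds of a given size were less detectable in mice and flies. The list of index sequences holds 2 entries with different sequences that can be read as S2-Control 2, and which of them its counts and peaks come from is not given. The labels say that 3 mice made up each group. They do not say whether cell libraries came from separate cultures or fly libraries from separate pools, and p-values there measure only the spread between these samples, which may be technical.

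The groups, the comparisons, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided) on the deposited counts after TMM normalization and the edgeR filter on low counts, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The S2 folate table was fitted alone. The 4 mouse groups shared a fit, as did the 4 fly groups, with group as the only term. This gave 8 comparisons of expression, and p-values were adjusted within each comparison, not across the 8. Levels are given as CPM (counts scaled to library size) computed here from the deposited counts after TMM, as mean ± SD with n = 3, and fold changes as log2 with the standard error (SE) of the fit. Levels of different tables were normalised separately. Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison, which numbered 18 in S2 cells, 23 in mouse and 20 in flies. Members past the threshold are counted after adjustment over all genes and after adjustment over the list alone. Medians of fly lists against genes of like length were taken after subtracting the running median over the 201 genes nearest in exonic length. R was 4.3.3.

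Genes were named by a fixed rule. It took the 10 largest folds in each direction among genes past 0.05 whose libraries did not overlap between groups and that reached 5 CPM in the higher group, without predicted or clone names. It took up to 4 members with the smallest p from each list that had a member past 0.05. Where no gene passed in a direction, it took the 3 genes of smallest p with at least 5 CPM, given as values only. Up to 10 peak regions in each direction were ranked by the lowest of the 3 scores. Any other gene in the text was chosen after its values were seen, which is said beside it.

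Peaks listed in several blocks were split into them, and each block kept the score of its whole peak. Blocks of the 6 libraries of a comparison were merged strand by strand with bedtools 2.31.1 where they shared at least 1 bp. A single peak can therefore give more than 1 region, as with lost regions of BicC and su(r). Counts of regions are thus not counts of peaks, and a short region can carry the score of a larger peak. A region was gained when called in 3 of 3 libraries of the first group and 0 of 3 of the second, and lost in the reverse case. The deposited score was used only to rank or halve the peaks of a list. Peak numbers were compared by an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. There were 6 peak comparisons. A region was assigned to the gene with the largest overlap with its exons on the same strand, from the exon coordinates of the count tables, so each named region overlaps exons of its gene, though wide regions, above all in mouse, also cover other sequence. Whether the peaks lie in untranslated or coding sequence was not analysed here, since no annotation with those parts was used. As a substitute chosen after seeing the data, peak positions were placed in 5 equal parts along the merged exons of genes with at least 1000 nt of exon. Coordinates are 1-based, in dm6 and mm39. Sequence motifs were not analysed here, since no genome sequence was used. The input fold changes of genes with gained or lost regions were compared with those of other genes that had any region by a two-sided permutation test with 100000 resamples.

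The analysis was tested on simulated counts with 67, 67 and 66 genes changed 1.5-, 2- and 4-fold. In the simulated S2 folate comparison (7708 genes), 36, 55 and 65 of them were recovered. In the simulated female mouse comparison (18286 genes), 0, 3 and 52 were recovered, and in the simulated GF-Folate comparison (12337 genes), 1, 20 and 59 were recovered. Unchanged genes made up 16 of 172 calls in the S2, 1 of 56 in the mouse and 6 of 86 in the GF-Folate simulation. The alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, a fit of the compared groups alone, a minimum fold of 1.5, leaving out each library in turn, better-scored peaks, and a required overlap of 50% of a region. Covariates and some other settings were added after seeing the data. Whether replicate numbers pair the samples was checked by correlating the deviations of same-numbered libraries from their group means. Among the pairs of groups compared, all 3 same-numbered libraries correlated above 0.1 only for GF-Control and WT-Control, with correlations of 0.32, 0.12 and 0.36 (and 0.30, 0.11 and 0.10 for GF-Control and WT-LP, which were not compared), where the pairing comes from the numbers in the labels and the data alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.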

Results

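Input mRNA was counted in 30 libraries and m6A peaks were listed for 30 immunoprecipitated libraries, in 10 conditions with n = 3 each. S2 cells were given folate (S2-Folate) or kept as controls (S2-Control). Brains came from female and male mice given folic acid (Female-Folate, Male-Folate) or in the control groups (Female-Control, Male-Control). Flies carried the labels WT-Control, WT-LP, GF-Control and GF-Folate, whose first parts are not explained in the labels and are used here as names. The shallowest libraries were S2-Control 2 with 3774003 counts and GF-Control 2 with 4344965 counts. In mouse brain, Xist, the RNA of the inactive X chromosome, was at 30.8 to 65.6 CPM in the 6 female libraries and at most 0.09 CPM in the male ones, and the Y-linked Ddx3y was at 38.4 to 49.7 CPM in males and 0 in females, so the sexes were as labelled.

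S2 cells given folate had higher counts of heat shock genes and of the single genes MtnA, Ldh and DptB. Hsp70Ba, a heat-inducible chaperone, rose from 2.63 ± 0.240 to 11.3 ± 0.233 CPM (log2 2.08, SE 0.213, adjusted p = 0.00230, n = 3). Hsp26, a small heat shock protein, rose from 67.7 ± 4.06 to 143 ± 0.988 CPM (1.08, SE 0.0873, adjusted p = 0.000444). MtnA, a metallothionein that binds copper and other metals, rose from 396 ± 21.4 to 983 ± 91.1 CPM (1.31, SE 0.0907, adjusted p = 0.000277), and Ldh, lactate dehydrogenase, from 14.8 ± 0.227 to 39.5 ± 1.81 CPM (1.42, SE 0.124, adjusted p = 0.000726). DptB, an antibacterial diptericin, rose from 13.2 ± 0.666 to 28.7 ± 2.28 CPM (1.11, SE 0.140, adjusted p = 0.00936). Hsp70Bc, Hsp70Bbb and Hsp70Bb rose by log2 1.92, 1.87 and 1.79, daw, a ligand of the activin branch of TGF-beta signalling, by 0.97 and fok by 0.65. Of 7786 genes tested with edgeR, 13 were higher and 0 lower, with 366 at an unadjusted p under 0.05. The other 3, lncRNA:Hsromega, CG5789 and CG9521, lie outside the naming rule and are named after their values were seen. DESeq2 called 25 higher and 0 lower. The lower genes of smallest p were cpo (log2 -0.44, adjusted p = 0.444), CG43103 (-0.56, adjusted p = 0.492) and egr (-0.30, adjusted p = 0.797), none past the threshold.

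The Hsp70 genes, Hsp26, MtnA and Ldh kept their calls without any one library of the S2 folate comparison. DptB lost its call without S2-Control 1 (adjusted p = 0.0538), S2-Control 3 (0.113), S2-Folate 1 (0.0564), S2-Folate 2 (0.101) or S2-Folate 3 (0.120), and daw and fok lost theirs without the same libraries, with the highest values of 0.264 and 0.302 without S2-Folate 1. The comparison called 8 genes without any of these 5 libraries and 65 without S2-Control 2, the shallowest, of which 55 were higher and 10 lower, and 54 (43 higher and 11 lower) with no filter on low counts. The deposited list of index sequences has 2 entries that can be read as S2-Control 2, and which of them was counted is not given.

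**Figure D1:**
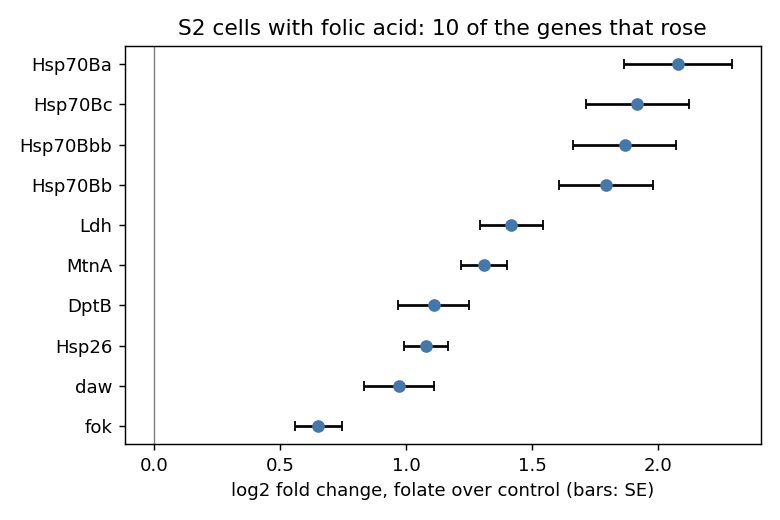
Log2 fold change of S2-Folate against S2-Control with its standard error for the 10 named genes that rose (n = 3 per group). Hsp70Ba is highest at 2.08 and fok lowest at 0.65.

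As a group, heat shock and stress genes had 12 of 14 members higher with folate and 5 past the threshold (9 adjusted over the list alone), a median log2 of 0.56 and camera adjusted p = 2.64e-13, against 0.0675 with an estimated correlation, which ended the call. Antimicrobial and immune genes had 14 of 16 members above 0, 1 past the threshold (4 adjusted over the list alone), a median of 0.46 and adjusted p = 9.74e-07 (adjusted p = 0.481 with an estimated correlation). Among them edin was at log2 1.08 (adjusted p = 0.251), PGRP-SA, a peptidoglycan receptor, at 0.44 (adjusted p = 0.722) and AttB, an attacin, at 0.90 (adjusted p = 0.916). DNA replication and cell cycle genes had 3 of 28 members above 0, 0 past the threshold with edgeR over all genes, a median of -0.15 and adjusted p = 1.17e-06 (adjusted p = 0.0675 with an estimated correlation). Ribosomal protein genes had 65 of 86 members above 0, a median of 0.10 and adjusted p = 0.000317 (0.503 with an estimated correlation, 0.0944 without S2-Folate 2). The one-carbon list, the enzymes that carry folate-bound and methyl groups, had 8 of 15 members above 0 (adjusted p = 0.640). The m6A machinery, the methyltransferase complex and reader proteins, had 7 of 10 (adjusted p = 0.309). Without S2-Control 2, the amino acid stress genes (adjusted p = 0.00207, against 0.173) passed upward and mitochondrial ribosomal protein genes (0.00164, against 0.537) downward.

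In mouse brain, no gene passed the threshold for folic acid in either sex. Ramp3, a receptor-modifying protein, had the smallest p in females at 26.2 ± 6.21 CPM with folic acid against 11.9 ± 1.59 CPM without (log2 1.14, SE 0.197, adjusted p = 0.944). Sox18, a transcription factor of blood vessel endothelium, was at 13.9 ± 2.57 against 7.25 ± 1.40 CPM (log2 0.94). Alb, the main plasma protein of liver, was at 26.7 CPM in Female-Folate 1 and at 0.64 and 3.31 CPM in the others of that group. Among genes with lower values, the immediate early gene Btg2 was at 7.15 ± 0.534 against 21.3 ± 12.4 CPM (log2 -1.57), Apold1 at log2 -1.16 and the chaperone gene Hspa1b at -0.76. In males the genes of smallest p were Ctsc (log2 0.59), Dvl2 (0.39), Zfp397 (0.47), Mid1-ps1 (-1.98), Mid1 (-1.27) and Plin4, a lipid droplet protein, at 2.48 ± 0.369 against 5.28 ± 0.794 CPM (-1.09). Of 18772 genes tested with edgeR, 0 passed in females (461 at an unadjusted p under 0.05) and 0 in males (263). DESeq2 called 0 genes in males and 6 higher in females, namely Alb, Gm52481, Ramp3, Prdm12, Ahsg and Fabp1, of which all but Alb and Ramp3 are named after their values were seen. Without Female-Control 3, Ccn3 (log2 -1.69, adjusted p = 0.00795) and Btg2 (-1.99, adjusted p = 0.0410) passed in females, and Ccn3 is likewise named after its values were seen.

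Cerebellar genes were low in all male libraries and in Female-Control 2, and high in the other 5 female libraries. Cbln3, a granule cell protein, was at 439, 4.09 and 898 CPM in the 3 Female-Control libraries, 542, 206 and 497 CPM in the Female-Folate libraries and at most 4.31 CPM in all males. Gabra6, a granule cell receptor subunit, was at 205, 1.69 and 299 CPM in Female-Control and 237, 80.4 and 152 CPM in Female-Folate, and Pcp2, a Purkinje cell gene, at 260, 2.49 and 289 CPM and 287, 94.2 and 185 CPM. Oxt, the oxytocin precursor of the hypothalamus, was at 42.9, 30.8 and 36.2 CPM in Male-Control and 36.7, 23.8 and 2.05 CPM in Male-Folate, and at 2.29, 12.5 and 0.21 CPM in Female-Folate. Its levels in Female-Control are not given here, so these values show no folic acid effect on Oxt in females. These genes belong to lists of brain regions fixed in advance and are named after their values were seen. Counts from mitochondrial DNA made up 7.64%, 10.1% and 15.2% of the Female-Control libraries and 14.7%, 16.1% and 17.4% of the Female-Folate ones. In males they made up 11.8%, 9.75% and 16.8% of Male-Control 1 to 3 and 8.53%, 9.00% and 9.53% of Male-Folate 1 to 3.

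**Figure D2:**
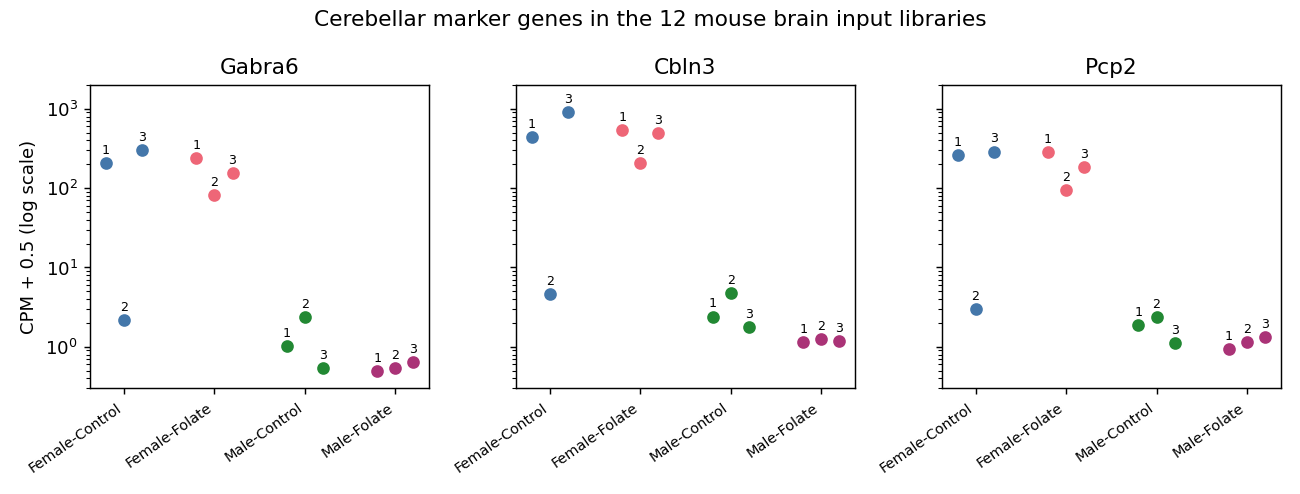
Levels of Gabra6, Cbln3 and Pcp2 (CPM + 0.5, log axis) in each mouse brain library, by group and replicate number. Female-Control 2 lies with the males, at 4.09 CPM or less for these genes, while the other female libraries lie at 80.4 CPM or more.

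In female brain, camera put 11 of 23 lists past 0.05 and fry put 0, and all 11 were lost with an estimated correlation. Genes encoded by mitochondrial DNA were higher with folic acid in 10 of 13 cases (median log2 0.69, adjusted p = 7.65e-05, and adjusted p = 0.331 with an estimated correlation), and this list alone of the 11 passed without any one library. Thalamus genes were higher in 8 of 8 (median 0.69, adjusted p = 7.65e-05, 0.508 with an estimated correlation), but not past 0.05 without Female-Control 2 (0.0722). Olfactory bulb genes had 7 of 9 members above 0 (0.45, adjusted p = 0.000779, 0.331 with an estimated correlation; 0.0512 without Female-Folate 1). Ribosomal protein genes had 12 of 87 above 0 (-0.36, adjusted p = 0.000585, 0.725 with an estimated correlation), which was lost without Female-Control 1 (0.487) or Female-Folate 3 (0.0946). The slope of library deviations on log2 gene length was -0.0257, 0.0438 and 0.132 in Female-Control 1 to 3. In Female-Folate 1 to 3 that slope was 0.0239, 0.113 and 0.164, and the female list differences were not set against genes of like length. Immediate early genes, switched on by neuronal activity, had 4 of 27 above 0 (-0.40, adjusted p = 0.00127, 0.725 with an estimated correlation), lost without Female-Control 2 (0.870) or Female-Folate 1 (0.315). Of the 11 lists, 6 passed without Female-Control 1, 6 without Female-Control 2, 8 without Female-Control 3, 7 without Female-Folate 1, 6 without Female-Folate 2 and 8 without Female-Folate 3. The cerebellum list had 3 of 13 members above 0 and a median of -0.11 while camera gave its direction as up (adjusted p = 0.167). It passed downward without Female-Control 2 (3.50e-05) and upward without Female-Control 1 (0.000160), Female-Control 3 (0.0231) or Female-Folate 2 (0.0111). The one-carbon list had 15 of 41 members above 0 (adjusted p = 0.170; 0.00983 without Female-Control 2 and 0.0399 without Female-Folate 1, downward) and the m6A machinery 14 of 24 (adjusted p = 0.700).

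In male brain, camera put 8 lists past 0.05, fry put 0, and none held with an estimated correlation. Hypothalamus and pituitary genes were lower with folic acid in all 14 members (median log2 -0.82, adjusted p = 0.0123, 0.723 with an estimated correlation) and genes encoded by mitochondrial DNA in 11 of 13 (2 above 0, median -0.70, adjusted p = 0.0123, 0.723 with an estimated correlation). Microglia genes were higher in 10 of 13 (median 0.22, adjusted p = 0.0123, 0.723 with an estimated correlation). The hypothalamus list lost its call without Male-Control 2 (0.0987), the mitochondrial list without Male-Control 1 (0.271) or Male-Folate 2 (0.101), and the microglia list without Male-Control 2 (0.0912), Male-Control 3 (0.127) or Male-Folate 2 (0.101). Without Male-Control 3, ribosomal protein genes turned from upward (59 of 87 above 0, adjusted p = 0.0375) to downward (3.03e-05). The slope of library deviations on log2 gene length was -0.154, -0.0891 and 0.0634 in Male-Control 1 to 3. In Male-Folate 1 to 3 that slope was -0.0790, -0.0834 and -0.109. No folic acid difference of a mouse list was set against genes of like length, so a trend with gene length was not separated from it. Of the 8 lists, 5 passed in the same direction without Male-Control 1, 1 without Male-Control 2, 4 without Male-Control 3, 8 without Male-Folate 1, 3 without Male-Folate 2 and 4 without Male-Folate 3. The one-carbon list had 26 of 41 members above 0 (adjusted p = 0.241) and the m6A machinery 11 of 24 (adjusted p = 0.241).

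The folic acid effect was then averaged over both sexes and compared between them. For the mean of both sexes, edgeR called 0 of 18772 genes, with 121 at an unadjusted p under 0.05, and DESeq2 called 0 of 36608. The genes of smallest p in it were Alb (log2 4.17), Ramp3 (0.45), Sox17 (0.27), Rny1 (-2.52), Rn18s-rs5 (-1.24) and Hspa1b (-0.44). Camera put 4 lists past 0.05, all lost with an estimated correlation, led by microglia genes (10 of 13 above 0, median 0.12, adjusted p = 0.00382, 0.958 with an estimated correlation; 0.682 without Female-Control 3 and 0.249 without Male-Control 3). In the test of the difference, female minus male, edgeR called 0 genes, with 997 at an unadjusted p under 0.05, and DESeq2 called 0. The genes of smallest p were Ramp3 (log2 1.39, SE 0.276, adjusted p = 0.672), Plin4 (2.17), Sox18 (1.37), Gtpbp4 (-4.86), Apold1 (-1.38) and Nfkbia (-0.77). Without Female-Control 3 the test called Ccn3 (log2 -2.37, adjusted p = 0.00560) and LOC118568506 (2.72, adjusted p = 0.0382), both named after their values were seen.

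Of the lists in the test of the difference, 12 passed camera and 0 passed with an estimated correlation or fry. Hypothalamus and pituitary genes differed most, with a median log2 of 2.09 and 14 of 14 members above 0 (adjusted p = 0.00184, 0.535 with an estimated correlation). Genes encoded by mitochondrial DNA had 11 of 13 above 0 (median 1.53, adjusted p = 0.000437, 0.443 with an estimated correlation), thalamus genes 8 of 8 (0.98, adjusted p = 0.000612, 0.535 with an estimated correlation) and olfactory bulb genes 8 of 9 (0.80, adjusted p = 0.00240, 0.443 with an estimated correlation). These 4 lists passed without any one of the 12 libraries. The mean of the hypothalamus and pituitary list was uneven within groups, at -0.29, 1.16 and -1.45 in Female-Folate 1 to 3 relative to the mouse mean on the log2 scale, and in females alone its camera call (adjusted p = 0.00803) was lost without Female-Folate 2 (0.683), Female-Control 2 (0.121) or Female-Control 3 (0.0715). No single member passed over all genes, and 3 thalamus members, Tcf7l2, Lef1 and Zfhx3, and the mitochondrial ND4L passed adjusted over the list alone, named after their values were seen. Across all 18772 genes the fold changes of females and males ran opposite (Spearman -0.53, Pearson -0.39), with the same sign in 27.6% of genes. Genes are not independent replicates, and the correlation was -0.06 without Male-Control 3 and -0.18 with no filter on low counts or with DESeq2. The opposite course thus rested largely on Male-Control 3. That library correlated at 0.931 and 0.956 with Male-Control 1 and 2, which correlated with each other at 0.989.

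Flies labelled GF-Folate were compared with GF-Control to see the response to folate in that background. Muc68E, a mucin, rose from 3.20 ± 1.63 to 20.4 ± 4.44 CPM (log2 2.74, SE 0.398, adjusted p = 0.00266, n = 3). Sgs3, a glue protein of the larval salivary gland, was at 10.1, 96.6 and 22.0 CPM against a mean of 0.34 CPM (adjusted p = 0.00382), and the larval cuticle gene Lcp4 at 33.8 against 0.56 CPM (adjusted p = 0.00533). PPO2, a phenol oxidase of crystal cells, rose to 19.8 ± 16.3 from 3.10 CPM (2.71, adjusted p = 0.00681). In the other direction, Send1, a gene of the sperm storage organs, fell from 123 ± 20.7 to 11.2 ± 8.19 CPM (-3.44, SE 0.563, adjusted p = 0.00387). The cuticle gene Cpr49Aa fell from 15.7 ± 4.20 to 2.16 ± 0.602 CPM (-2.85, SE 0.395, adjusted p = 0.00215). The gut lysozyme genes LysB, LysD and LysE, which share sequence, fell by 2.26, 2.16 and 1.82 on the log2 scale (LysB not when GF-Folate and GF-Control were fitted alone, adjusted p = 0.0513). Of 12491 genes, 1020 were higher and 1088 lower, with 4094 at an unadjusted p under 0.05.

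The size of that count rested on single libraries and on the fit. It was 446 without GF-Control 3, 610 without GF-Control 1 and 3759 (2095 higher and 1664 lower) without GF-Folate 1, of which 1964 were shared with the 2108. It was 461 (294 higher and 167 lower) when GF-Folate and GF-Control were fitted alone, 1872 (1110 higher and 762 lower) with no filter on low counts, 2758 (1337 higher and 1421 lower) with DESeq2 and 3933 with the roX1 level as a covariate, a setting chosen after the data were seen, of which 1001 were shared. Of 69 calls of named genes, 34 held in the fit of 2 groups, 40 with roX1 as a covariate and 33 without any one library. Fewest were kept without GF-Control 3 (34) and GF-Control 1 (40), and 69 without GF-Folate 1. Genes of this comparison named by the rule kept theirs in these fits unless a further value is given.

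Library GF-Folate 1 stood apart from the 2 other GF-Folate libraries. The yolk protein genes Yp1, Yp2 and Yp3, made in the fat body and ovary of females, were at 240, 517 and 265 CPM in it, against 3285, 6550 and 7527 CPM in GF-Folate 2 and 3635, 6862 and 5883 CPM in GF-Folate 3. The roX1 RNA, part of the male dosage compensation complex, was at 814 CPM in it, 349 and 402 CPM in the other GF-Folate libraries and 184 to 185 CPM in GF-Control. The mean of 14 ovary genes was -3.28 in it against 0.48 and 0.39 in the others, relative to the fly mean on the log2 scale, and that of 14 testis genes 1.14 against 0.41 and 0.46. These genes were named after their values were seen.

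In GF-Folate flies, of 72 mitochondrial ribosomal protein genes, 38 fell and 0 rose (44 adjusted over the list alone), with 3 above 0 and a median log2 of -0.71. mRpS14 fell from 61.4 ± 7.10 to 27.2 ± 4.65 CPM (log2 -1.18, SE 0.171, adjusted p = 0.00266), and mRpL27, mRpL30 and mRpS35 fell by 1.38, 1.14 and 1.11. Of 92 cytoplasmic ribosomal protein genes, 43 fell and 0 rose (55 fell and 1 rose adjusted over the list alone), with a median of -0.56. RpL36 fell from 1365 ± 140 to 506 ± 136 CPM (-1.43, SE 0.183, adjusted p = 0.00191), and RpLP2, RpL23 and RpL8 fell by 1.28, 1.13 and 1.03. In GF-Folate 1 the mean of the ribosomal list was -0.80, against -0.22 and -0.08 in the other GF-Folate libraries, and that of the mitochondrial ribosomal list -0.79, against -0.18 and -0.15. Of 21 one-carbon genes, 3 were above 0, and 4 fell (8 adjusted over the list alone), with a median of -0.61, among them Cbs (-1.01, adjusted p = 0.0254), the serine hydroxymethyltransferase gene Shmt, which loads folate with a carbon unit (-0.80, adjusted p = 0.0277), and CG10623 (-0.71, adjusted p = 0.0224). Of 16 genes of purine and thymidylate synthesis, 3 fell (4 adjusted over the list alone), among them the adenylosuccinate synthase gene AdSS (log2 -0.83, adjusted p = 0.00642) and the pyrophosphatase gene Nurf-38 (-0.86, SE 0.123, adjusted p = 0.00253, from 353 ± 9.08 to 195 ± 22.1 CPM), with a median of -0.46. The camera tests gave adjusted p = 6.37e-18, 5.79e-15, 0.00112 and 0.00112 for these 4 lists in that order, and each passed without any one library. With an estimated correlation they gave adjusted p = 0.619, 0.696, 0.619 and 0.619, which ended the calls, and fry gave 0.0175, 0.0378, 0.0175 and 0.0378. Against genes of like length the 4 medians were -0.70, -0.54, -0.58 and -0.60. Cbs lost its call without GF-Control 1 (0.0992) or GF-Control 3 (0.0970), CG10623 without GF-Control 1 (0.0801) or GF-Control 3 (0.100), and Shmt without GF-Control 1 (0.0566), GF-Control 3 (0.127), GF-Folate 2 (0.0625) or GF-Folate 3 (0.0844). In the fit of 2 groups, Cbs (0.123), CG10623 (0.121), Shmt (0.0811), AdSS (0.0563), RpL8 (0.0571) and mRpS35 (0.0516) did not pass, and with roX1 as a covariate Cbs (0.563), CG10623 (0.516), AdSS (0.0915) and RpL8 (0.0572) did not.

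Of 36 neuronal and synaptic genes, 12 rose and 1 fell in GF-Folate flies (19 and 1 adjusted over the list alone), with a median log2 of 0.53, or 0.24 against genes of like length. The synaptic vesicle priming gene unc-13 rose from 59.2 ± 6.42 to 131 ± 10.8 CPM (log2 1.14, SE 0.148, adjusted p = 0.00195) and the presynaptic calcium channel gene cac from 22.9 ± 1.37 to 56.8 ± 10.1 CPM (1.31, SE 0.171, adjusted p = 0.00196). The sodium channel gene para rose by 1.01 (adjusted p = 0.00554) and the GABA receptor gene Rdl from 31.3 ± 2.32 to 76.8 ± 28.2 CPM (adjusted p = 0.00729). The list passed camera (adjusted p = 0.000198), but not with an estimated correlation (adjusted p = 0.821) or without GF-Folate 1 (0.137). The photoreceptor genes chp (log2 1.20, adjusted p = 0.00582) and norpA (0.74, adjusted p = 0.00650) and the glial gene moody (1.11, adjusted p = 0.00736) also rose. With roX1 as a covariate, para (adjusted p = 0.0881), Rdl (0.184), chp (0.103) and moody (0.0847) did not pass. Testis genes were above 0 in 14 of 14 cases and 2 rose (5 adjusted over the list alone; median 0.61, adjusted p = 0.00457, 0.821 with an estimated correlation, 0.168 without GF-Folate 1). Ovary genes had 12 of 14 members above 0 and a median of 0.52 while camera gave their direction as down (adjusted p = 0.960; upward at 0.000478 without GF-Folate 1). The mean of the ovary list was far lower in GF-Folate 1 than in the other GF-Folate libraries, so neither direction describes all libraries of that group. DNA replication and cell cycle genes likewise had a median of 0.29 while camera gave down (adjusted p = 0.758), upward at 2.22e-07 without GF-Folate 1 and downward at 0.0126 without GF-Folate 2.

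The m6A machinery in GF-Folate flies had 3 of 10 members above 0, a median log2 of -0.25 and adjusted p = 0.130 (0.0387 without GF-Folate 2 and 0.0351 without GF-Folate 3). Flacc, a subunit of the methyltransferase complex, was the only member that fell (log2 -0.73, SE 0.183, adjusted p = 0.0208, from 103 ± 5.59 to 61.9 ± 12.6 CPM), with adjusted p = 0.0728 without GF-Control 1, 0.0892 without GF-Control 3, 0.0922 in the fit of 2 groups and 0.470 with roX1 as a covariate. The catalytic subunit gene Mettl3 was at -0.43 (adjusted p = 0.184), Hakai at -0.71 (adjusted p = 0.113) and the reader gene Ythdc1 at -0.37 (adjusted p = 0.105). Heat shock and stress genes had 3 of 19 members above 0, 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.0104, 0.619 with an estimated correlation, 0.0768 without GF-Folate 3). Digestive enzyme genes had 7 of 25 above 0 and 3 fell, over all genes and adjusted over the list alone (adjusted p = 0.0104, 0.821 with an estimated correlation, 0.192 without GF-Folate 1). The asparagine synthetase gene AsnS fell from 113 ± 10.7 to 51.5 ± 15.6 CPM (log2 -1.14, SE 0.231, adjusted p = 0.00899) and the lipoprotein gene apolpp rose from 1131 ± 145 to 2273 ± 339 CPM (1.01, SE 0.177, adjusted p = 0.00484). In the fit of 2 groups AsnS did not pass (0.0560), and with roX1 as a covariate neither AsnS (0.192) nor apolpp (0.0619) did. Antimicrobial and immune genes had 14 of 29 members above 0 and 3 fell, over all genes and adjusted over the list alone (adjusted p = 0.0672; 0.0158 without GF-Control 1 and 1.46e-07 without GF-Folate 2).

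Flies labelled WT-LP differed from WT-Control by no gene past the threshold. The larval serum protein genes Lsp1alpha, at 10.9 ± 0.641 against 2.10 ± 1.17 CPM (log2 2.43, SE 0.368, adjusted p = 0.268), and Lsp1beta, at 68.2 ± 12.2 against 17.7 ± 10.1 CPM (1.94, SE 0.344, adjusted p = 0.602), had the smallest p among genes with higher values. They were followed by Fbp1, the receptor for these storage proteins, at 122 ± 9.21 against 20.2 ± 16.4 CPM (2.59, SE 0.504, adjusted p = 0.774). The genes with lower values were Fst, a frost-induced gene (log2 -1.23), CG13947 (-0.83) and CG6041 (-0.78). Of 12491 genes tested with edgeR, 0 passed, with 303 at an unadjusted p under 0.05. DESeq2 called 7 genes, all higher: Lsp1alpha, Lsp1beta, Fbp1, Alp8, Cpr49Ac, Fbp2 and Lsp2, the last 4 named after their values were seen. Fbp1 and Lsp1beta (each with adjusted p = 0.0338) passed without WT-Control 3, and Lsp1alpha (2.45, adjusted p = 0.0314) without GF-Folate 1, a library of another group in the same fit.

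As a group, fat body genes were higher in WT-LP flies and the only list to pass with an estimated correlation. Of 15 members, 12 were above 0 and 0 passed over all genes with edgeR (5 at an unadjusted p under 0.05 and 5 adjusted over the list alone), while DESeq2 called Lsp1alpha, Lsp1beta, Fbp1, Fbp2 and Lsp2, with a median log2 of 0.32, camera adjusted p = 1.53e-08, adjusted p = 0.0456 with an estimated correlation and fry adjusted p = 0.0341. With DESeq2 these 5 lay at log2 1.76 to 2.625, well above the list median. Lsp1alpha, Lsp1beta and Lsp2 among them are larval serum protein genes, so the values do not show a shift of fat body genes in general. Neuronal and synaptic genes were lower in 33 of 36 (3 above 0, median -0.22, adjusted p = 0.000100), testis genes in 14 of 14 (0 above 0, -0.18, adjusted p = 0.0248), and mitochondrial ribosomal protein genes were higher in 54 of 72 (0.08, adjusted p = 0.00546), and each of these gave adjusted p = 0.901 with an estimated correlation. The testis list lost its call without WT-Control 1 (0.0874), WT-Control 3 (0.385), WT-LP 1 (0.869) or WT-LP 3 (0.231), and the mitochondrial ribosomal list without WT-Control 3 (0.385), WT-LP 1 (0.356) or WT-LP 3 (0.222). The mean of the testis list was -0.89, 0.08 and -0.67 in WT-LP 1 to 3 and -0.24, -0.47 and -0.02 in WT-Control 1 to 3, relative to the fly mean on the log2 scale. The roX1 level, looked at after the data were seen, was 157, 299 and 134 CPM and 238, 203 and 308 CPM in the same order. The m6A machinery had 9 of 10 members above 0 (adjusted p = 0.262; 0.0156 without WT-LP 2) and the one-carbon list 10 of 21 (adjusted p = 0.710).

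Between GF-Control and WT-Control flies, Fst rose from 10.0 ± 2.68 to 178 ± 18.1 CPM (log2 4.17, SE 0.297, adjusted p = 5.36e-05, n = 3). Hsp70Bb rose from 1.26 ± 0.843 to 51.0 ± 17.8 CPM (5.24, SE 0.471, adjusted p = 8.64e-05), Hsp68 by 2.75 and the small heat shock gene Hsp23 from 23.1 ± 1.34 to 112 ± 20.5 CPM (2.28, SE 0.228, adjusted p = 0.000126). Fbp1 rose from 20.2 ± 16.4 to 423 ± 143 CPM (4.38, SE 0.543, adjusted p = 0.000299) and the lipid droplet gene Lsd-1 from 49.6 ± 4.37 to 270 ± 22.5 CPM (2.45, SE 0.204, adjusted p = 6.95e-05). Muc12Ea, a mucin that overlaps CG9400, fell from 254 ± 166 to 8.67 ± 3.58 CPM (-4.84, SE 0.834, adjusted p = 0.00170). The chromosome segregation genes thr (-2.80, adjusted p = 0.00641) and Spc105R (-2.60, adjusted p = 0.00188), and Ptip (-2.58, adjusted p = 0.00113), fell. Of 12491 genes, 1882 were higher and 1672 lower, with 5205 at an unadjusted p under 0.05. The count was 1856 without GF-Control 3, 1909 without WT-Control 1, 2095 without WT-Control 2, 2247 without GF-Control 1, 5708 without GF-Folate 1, a library of neither group, 6120 when the 2 groups were fitted alone and 7060 with roX1 as a covariate. Of 89 calls of named genes, 59 held without any one library, and genes named here without a further value were among them.

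**Figure D3:**
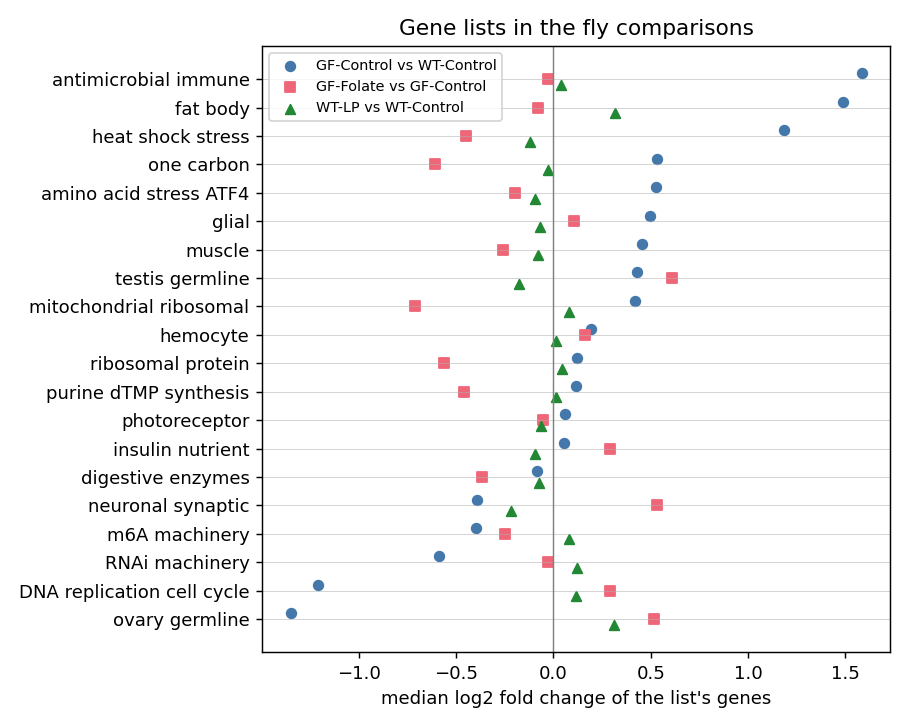
Median log2 fold change of the members of 20 gene lists in the 3 fly comparisons, 1 point per list and comparison. Mitochondrial ribosomal protein genes lie at 0.42 in GF-Control against WT-Control and at -0.71 in GF-Folate against GF-Control, but at -0.02 and -0.70 against genes of like length.

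By group, heat shock and stress genes rose in 11 of 19 cases (11 adjusted over the list alone; median log2 1.19) and fat body genes in 8 of 15 (8 adjusted over the list alone; 1.49) in GF-Control flies. Antimicrobial and immune genes rose in 15 of 29 (18 adjusted over the list alone; 1.59), among them IM1 from 34.1 ± 6.10 to 145 ± 20.4 CPM (2.09, SE 0.216, adjusted p = 0.000126) and the NF-kappaB gene Rel (0.84, adjusted p = 0.00470). One-carbon genes rose in 9 of 21 and fell in 1 (10 and 1 adjusted over the list alone; 0.53). Gnmt, which uses S-adenosylmethionine to methylate glycine, rose from 14.2 ± 6.03 to 66.2 ± 11.7 CPM (2.22, SE 0.311, adjusted p = 0.000576) and Shmt from 228 to 510 ± 94.8 CPM (1.16, SE 0.218, adjusted p = 0.00269). Mitochondrial ribosomal protein genes rose in 20 of 72 (20 adjusted over the list alone; 0.42). Neuronal genes rose in 3 of 36 and fell in 15 (3 and 17 adjusted over the list alone, 1 and 13 with the replicate number as a block; -0.40), among them unc-13 (-1.48, SE 0.149, adjusted p = 0.000126) and cac (-1.23, adjusted p = 0.000555). DNA replication and cell cycle genes were below 0 in all 28, of which 6 fell (0 adjusted over the list alone; -1.21). Only Orc5 of these 6 (-1.57, adjusted p = 0.0139, but 0.0567 without WT-Control 1 and 0.0531 without GF-Control 1) passed with the block, where DNApol-alpha180 gave 0.0537 and Orc2 0.0706, and at most 3 members fell without any one library of the 2 groups. Camera gave adjusted p = 1.52e-05, 0.000134, 8.50e-05, 0.0208, 0.000644, 0.00147 and 8.50e-05 for these 7 lists in that order, each past 0.05 without any one library. With an estimated correlation they gave adjusted p = 0.170 for the first and second and 0.896 for the others, which ended all 7 calls. Against genes of like length the medians were 1.00, 1.52, 1.12, 0.24, -0.02, -0.03 and -1.12, so the differences of the mitochondrial ribosomal and neuronal lists were not seen apart from the trend with gene length, and that of the one-carbon list was smaller.

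Cytoplasmic ribosomal protein genes did not pass as a group between GF-Control and WT-Control, with 58 of 92 above 0, 10 higher and 2 lower (0 adjusted over the list alone, 4 and 1 with the block) and adjusted p = 0.451. Their median log2 was 0.12, or -0.22 against genes of like length. The m6A machinery had 4 of 10 members above 0 and a median log2 of -0.40 (adjusted p = 0.187), and 2 members fell, also when adjusted over the list alone (1 with the block). The complex subunit gene vir, whose exons overlap those of Mthfs, fell from 55.1 ± 3.40 to 31.9 ± 5.63 CPM (-0.78, adjusted p = 0.0162), but not past 0.05 without WT-Control 2 (0.0606), GF-Control 1 (0.0587) or GF-Control 2 (0.0638). The reader gene Ythdf fell from 136 ± 19.6 to 72.2 ± 7.88 CPM (-0.92, adjusted p = 0.0368), but gave 0.0711 with the replicate number as a block and lost its call without WT-Control 1 (0.0959), WT-Control 2 (0.117), GF-Control 1 (0.0777), GF-Control 2 (0.0846) or GF-Control 3 (0.130). The complex genes nito (-0.93, adjusted p = 0.0914) and fl(2)d (-0.48, adjusted p = 0.118) did not pass. Ovary genes had 2 of 14 members above 0 and 4 fell (5 adjusted over the list alone), of which bam, gcl, Cp18 and Cp19 all lost their calls with the block (0.0790, 0.0773, 0.0755 and 0.0891), with a median of -1.35 and adjusted p = 0.104 (0.00112 without GF-Folate 1).

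Fold changes were compared between experiments across genes, which are not independent replicates. GF-Folate against GF-Control ran opposite to GF-Control against WT-Control over 12491 genes (Pearson and Spearman -0.47), with 65.9% of genes of opposite sign. These comparisons share the GF-Control libraries, and unchanged groups simulated against them 100 times gave a mean Pearson of -0.53 and 67.3% of opposite sign. The covariance of -0.274 lay beyond the lowest simulated value of -0.0846 (mean -0.0769), a difference of -0.197. Of the 1672 genes lower in GF-Control, 551 were higher in GF-Folate, and of the 1882 higher ones, 696 were lower in GF-Folate. Higher in both were 3 genes, and lower in both 3. Sharing the GF-Control libraries by itself favours this pattern. When each GF-Control library was used in only one of the comparisons, in a test chosen after the data were seen with 1 library against 2 in 6 ways, the covariance was -0.2765 to -0.2002 and the Pearson correlation -0.42 to -0.24. Taking out the median of genes of like length kept 82.4% to 90.0% of that covariance. GF-Folate against GF-Control and WT-LP against WT-Control correlated at Spearman -0.30 (Pearson -0.23; -0.10 without GF-Folate 1 and -0.14 without WT-LP 3).

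Peak lists held 36071 to 55359 peaks per fly or S2 library and 122089 to 146948 per mouse library. With 3 against 3 the smallest exact p is 0.1, so no difference in peak number could pass 0.05. Every GF-Folate library (53152 to 55276) and every WT-Control library (54653 to 55134) held more peaks than every GF-Control library (50164 to 52585). Input counts were also higher in every GF-Folate library (13107389 to 23665385) than in every GF-Control library (4344965 to 10947883). WT-Control 2, with 6653943 input counts, nevertheless held more peaks than the deeper GF-Control 1 and 3. Depth of the immunoprecipitated libraries is not given here, so depth was not separated from these differences. GF-Folate libraries held 54474 ± 1154 peaks against 51724 ± 1354 in GF-Control, 5.32% more, and WT-Control held 54869 ± 244, with GF-Control at -5.73% beside it, each with exact permutation p = 0.1. The differences were 6.79% for S2 folate (exact p = 0.5), 1.05% in female (exact p = 0.9) and -2.26% in male brain (exact p = 0.6), and 0.0990% for WT-LP (exact p = 0.9). The last 3 changed sign without single libraries: females without Female-Control 2 (-2.30%) or Female-Folate 3 (-0.526%), males without Male-Folate 3 (0.378%), and WT-LP without WT-LP 3 (-0.298%) or WT-Control 2 (-0.0979%). Among peaks past the median score, the differences were -4.45% for S2 folate (exact p = 0.6), 11.7% in females (exact p = 0.4), and 0.763% in males (exact p = 1). They were 18.1% for GF-Folate (exact p = 0.1), 2.02% for WT-LP (exact p = 0.9) and -18.0% for GF-Control against WT-Control (exact p = 0.3, with the groups overlapping).

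Regions called in all 3 libraries of one group and none of the other were few beside the regions called in all 6. In GF-Folate against GF-Control, 866 regions were gained and 150 lost of 98197, with 29391 in all 6 libraries. The 10 gained ones of highest rank overlapped, among others, exons of Nmnat, an NAD synthesis and neuroprotective enzyme (3R 24946823 to 24946833), the neuronal transcription factor gene acj6 (X 15377587 to 15377593), dbr (2L 68085 to 68195), the translational repressor gene pum (3R 9232679 to 9232856), Sgs3 (3L 11512221 to 11512262) and the potassium channel gene Shab (3L 2956821 to 2956873). Their lowest deposited scores were 3.53, 3.51, 3.17, 3.12, 3.02 and 3.02, and the other 4 overlapped exons of RhoGAP5A (3.47), Exn (3.38), Oatp58Dc (3.07) and cnc (2.96). The lost ones included the cathepsin gene cathD (2R 7815689 to 7815726, score 2.88) and the pyrimidine-degrading enzyme gene su(r) (X 9200149 to 9200196, score 1.94), whose input counts were also lower (log2 -0.65 and -1.23, adjusted p = 0.00935 and 0.00583). Of the 30 genes with lost regions whose input passed 0.05, however, 19 were higher and 11 lower. Without GF-Control 1 to 3 in turn, which eases losses, this comparison had 1972 regions gained and 543 lost, 1244 and 825, and 1595 and 631. Gains and losses were thus most even without GF-Control 2, which had the fewest input counts and the fewest peaks of these libraries. Library depth was not separated from the excess of gained regions. In GF-Control against WT-Control, 327 regions were gained and 833 lost of 100057, with 28705 in all 6. Leaving out 1 GF-Control library eases gains, from 3 of 3 to 2 of 2 libraries, and the balance was then 893 gained and 1869 lost, 1325 and 1181, and 1017 and 1402 for GF-Control 1 to 3. Gained ones included regions of the ATP synthase subunit gene blw (2R 22801342 to 22801370, score 6.04), of mdy, a triglyceride synthesis enzyme (2L 16820531 to 16820559, 3.51) and of the collagen gene Col4a1 (2L 5036072 to 5036208, 3.07). The input of mdy and Col4a1 was also higher (log2 0.82 and 1.26, edgeR adjusted p = 0.00439 and 0.000722). Of the 77 genes with gained regions whose input passed 0.05, 37 were higher and 40 lower. For mdy no values under other settings are given here. Lost ones included regions of the actin gene Act5C (X 5900861 to 5901013, 4.27), the germline translational regulator gene BicC (2L 16044314 to 16044361, 4.02) and Muc12Ea (X 14277935 to 14278484, 3.22), whose input had fallen by 4.84.

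**Figure D4:**
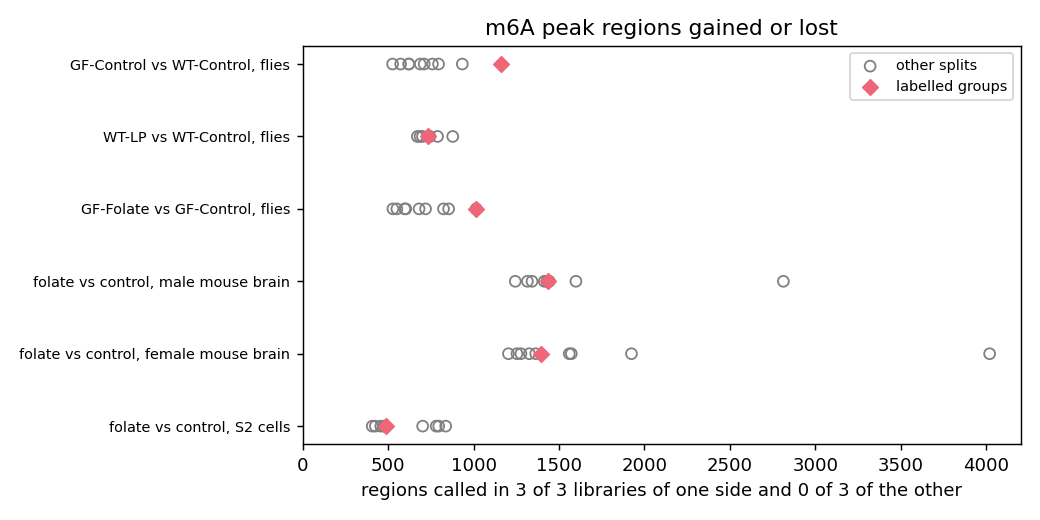
Number of peak regions called in 3 libraries and not in the 3 others, for the labelled groups (diamonds) and the 9 other splits of the same 6 libraries (open circles) in 6 comparisons. GF-Control against WT-Control (1160) and GF-Folate against GF-Control (1016, beside 1015) lie highest in their rows, and the labelled groups of the other 4 comparisons do not.

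In the other comparisons the gained and lost regions were 380 and 105 of 86708 for S2 folate, 836 and 557 of 179482 in female brain, 640 and 793 of 174181 in male brain, and 323 and 411 of 101674 for WT-LP. Leaving out 1 control library eases losses in the same way, and the S2 folate balance was then 940 gained and 506 lost, 506 and 962, and 857 and 435 for S2-Control 1 to 3. In female brain it was 1680 and 1533, 1541 and 2523, and 3915 and 3380 for Female-Control 1 to 3. Leaving out a library of the first group eases gains. The balance was then 2076 and 1552, 2903 and 1617, and 2158 and 1672 for Male-Folate 1 to 3. For WT-LP 1 to 3 it was 1204 and 984, 1343 and 712, and 1192 and 801. Named regions included the peroxiredoxin gene Jafrac1 (X 13330399 to 13330416, gained, score 4.38) for S2 folate. In female brain they included Gcnt4 (chromosome 13, 97063287 to 97063309, gained, 3.24) and Tmem163 (chromosome 1, 127419354 to 127423460, lost, 2.64). In male brain the gained region of highest rank was that of Cd226 (chromosome 18, 89265449 to 89281411, score 2.40). That region is wide, and Cd226 was not among the genes tested for input, so it has no input fold change. Slc25a32, the mitochondrial folate carrier, is given for its link to folate. It had a gained region of lower rank (chromosome 15, 38954950 to 38955349, score 2.11) with its input at log2 0.02. This was 1 of the 640, in a comparison where 5 of 10 splits gave at least as many gained and lost regions. For WT-LP they included the trophic factor gene Manf (3R 16349675 to 16349799, gained, 2.69) and Tim17b (3R 3735357 to 3735446, lost, 3.53). By chance alone 10% of regions found in exactly 3 of 6 libraries would fall on the labelled groups, in one direction or the other, and regions a few nt long can arise where peak edges differ between libraries.

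Genes with gained regions in GF-Folate flies also had higher input counts. The mean log2 fold change of 465 such genes exceeded that of the other genes with regions by 0.276 (permutation p = 1e-05, the smallest possible, adjusted p = 6.00e-05 over 12 tests), 68.0% were above 0, and of the 98 past 0.05, 74 rose and 24 fell. Among the named ones the input of Sgs3 was at log2 6.66 (adjusted p = 0.00382), that of the transcription factor gene cnc at 0.64 (adjusted p = 0.00978) and that of dbr at 0.94 (adjusted p = 0.0231). Nmnat was at -0.19, RhoGAP5A at -0.34 and Exn at -0.29. Where the input moved with the region, a change of m6A cannot be told apart from a change of RNA level. The input calls of cnc, dbr, cathD and su(r) were not tested under other settings. The 599 genes with lost regions in GF-Control against WT-Control were lower by the same measure (difference -0.332, adjusted p = 6.00e-05; 159 fell and 76 rose of 235 past 0.05). Smaller differences passed in female brain for 346 genes with lost regions (0.0751, adjusted p = 0.00555) and in male brain for 445 genes with gained regions (-0.0614, adjusted p = 0.00220), and the other 8 tests did not pass. In each sex, 5 of 10 splits of the libraries gave at least as many gained and lost regions as the labelled groups. These tests shuffled genes, which are not independent replicates, so their p-values measure no spread between samples. The shares of peaks in the first and the last of 5 equal parts of exons were compared, and here too no difference could pass 0.05. The first part held 20.2% ± 0.0980 of peaks in GF-Control, 20.5% ± 0.0676 in WT-Control, 20.5% ± 0.132 in GF-Folate and 20.7% ± 0.0422 in WT-LP, and GF-Control lay apart from WT-Control and from GF-Folate, and WT-LP from WT-Control, in every library (exact permutation p = 0.1 each). Among the better-scored peaks that share was 0.634 points higher, not lower, in GF-Control than in WT-Control, 0.0573 points higher in GF-Folate than in GF-Control and 0.526 points higher in WT-LP than in WT-Control. The last part held 32.6% ± 0.327 of fly peaks in GF-Control and 31.3% ± 0.212 in WT-Control (exact permutation p = 0.1, with the difference at -0.510 points among the better-scored peaks), 31.7% ± 1.13 in GF-Folate (exact p = 0.4), and 21.4% and 21.3% in female mouse brain with and without folic acid.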

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

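The counts over other splits of the samples, the count of cerebellar members, the covariance on separate GF-Control libraries, before and after taking out length, and the medians against genes of like length of neuronal genes and, between GF-Control and WT-Control, of mitochondrial ribosomal protein genes were tests chosen after the results were seen.

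In the test of the difference between the folic acid effects of female and male mice, 12 of 23 gene lists passed camera, and hypothalamus and pituitary genes had a median log2 difference of 2.09, a difference between groups. Within Female-Folate the mean of that list was -0.29, 1.16 and -1.45 by library, relative to the mouse mean on the log2 scale, and its call in females alone was lost without Female-Folate 2 (adjusted p = 0.683). None of the 12 passed with an estimated correlation (adjusted p = 0.535 for hypothalamus and pituitary genes), and edgeR called 0 genes in it (997 at an unadjusted p under 0.05, 0 with DESeq2).

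Gene changes from WT-Control to GF-Control ran opposite to those from GF-Control to GF-Folate. The GF-Control libraries stand on both sides, but the covariance of -0.274 was still -0.2765 to -0.2002 when each of them was used on a single side, which argues against that sharing as the whole cause. For genes as a whole a trend with gene length is argued against by the 82.4% or more of that covariance kept against genes of like length, and between GF-Folate and GF-Control by the medians of mitochondrial ribosomal (-0.70, -0.71 before) and ribosomal protein genes (-0.54, -0.56 before). Between GF-Control and WT-Control that trend may account for the medians of mitochondrial ribosomal (-0.0165, SE 0.0602, 0.42 before) and neuronal genes (-0.0282, SE 0.0924, -0.40 before), and for neuronal genes between GF-Folate and GF-Control (0.24, SE 0.106, 0.53 before) it cannot be told apart, as the standard error spans 50% of the earlier value. The SE here is that of a median over the genes of a list, not that of the fit. Genes are not independent replicates, so it measures no spread between samples and may be too small. The make-up of the samples, with GF-Folate 1 apart in yolk genes and roX1, a shift common to all GF-Control libraries, and a response to folate stay open.

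Cerebellar genes differed among the 3 Female-Control libraries. Of the 13 members, 11 were at least 2-fold higher in both Female-Control 1 and 3 than in Female-Control 2, against 2.49% of all genes. This count was chosen after low levels in Female-Control 2 had been seen, so it describes the pattern and cannot test its cause. An unequal share of cerebellum in the tissue taken may be a candidate cause. A trend with gene length is argued against, as the median difference of the list between Female-Control 1 and 2 was log2 4.20 against genes of like length (4.12 before). Female and male groups differed in the same genes, and a difference in dissection there cannot be separated from sex in this design. No biological explanation was tested.

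With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For expression, in S2 folate (13 genes), GF-Folate against GF-Control (2108) and GF-Control against WT-Control (3554), 1 of 10 splits, the labelled one, called as many, and the highest other called 0. For female brain, male brain and WT-LP with 0 genes (10 of 10 splits), and for the mean of both sexes and the difference between them with 0 genes (100 of 100 splits), every split must call as many, which says nothing about chance. The highest other splits called 291, 0, 0, 136 and 105 genes, and those of 291, 136 and 105 point to a structure of the samples. At an unadjusted p under 0.05, 2 of 10 splits called at least the 366 genes of S2 folate (highest other 387), 7 of 10 the 461 of female brain (3661), 5 of 10 the 263 of male brain (1946), 4 of 10 the 303 of WT-LP (1157), and 1 of 10 the 4094 of GF-Folate against GF-Control (1971) and the 5205 of GF-Control against WT-Control (411). By that count 92 of 100 splits called at least the 121 genes of the mean (5688) and 42 of 100 at least the 997 of the difference (4319), so that chance cannot be excluded there.

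For gained and lost peak regions, 5 of 10 splits gave at least the 485 of S2 folate (highest other 837), the 1393 of female brain (4020) and the 1433 of male brain (2813). For WT-LP, 7 of 10 gave at least 734 (878). For GF-Folate against GF-Control (1016, highest other 1015) and GF-Control against WT-Control (1160, highest other 934), 1 of 10 did. The highest split of female brain, several times the real count, points to a structure of the samples other than the labels.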

How the results depend on the processing

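Tests chosen after the data were seen were those with roX1, cerebellum or gene length as a covariate, those without GF-Folate 1 where it was not compared, those of lists with a block or without each library, those of exonic parts of peaks, peaks of at most 1000 nt and exon positions, and the settings for agreement between experiments. Causes were not tested except where fewer samples or genes explain a change. The shallow S2-Control 2 and GF-Control 2 limit what low-count genes can show. No comparison of peak numbers or regions was adjusted for library depth. A test of m6A enrichment over input was not run.

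Of 168 calls of named genes, 167 kept direction and side of the threshold with DESeq2 (1 had no adjusted p), 167 with RLE normalization, 162 with no filter on low counts and 142 with the replicate number as a block. Of 158 in flies, 123 did in fits of 2 groups and 129 with roX1 as a covariate. Of 1097 calls in fits without 1 library, 861 were kept and 0 reversed.

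Gene counts for S2 folate (13) were 54 with no filter, 25 with DESeq2 and 8 to 65 without single libraries. In female brain (0) they were 6 with DESeq2 and 0 to 2 without single libraries, as was the range for the sex difference (0 to 2). For GF-Folate (2108) they were 1308 with the block, 461 in a fit of 2 groups, 3933 with roX1 and 446 to 3759 without single libraries. For WT-LP (0) they were 7 with DESeq2 and 0 to 2 without single libraries (1 without GF-Folate 1). For GF-Control against WT-Control (3554) they were 2827 with the block, 6120 in a fit of 2 groups, 7060 with roX1 and 1856 to 5708 without single libraries, and beyond the genes and list counts given with their blocked values, the block ended no call of a gene and moved no list count by over 1.5 times among those printed for that pair. Libraries correlated best with their own number in 2 of 3 S2 folate cases, 7 of 18 mouse cases and 8 of 18 fly cases.

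Of 58 camera list calls, 1 held with an estimated correlation, and fry made 14. With the roX1 covariate, GF-Folate values turned to log2 -0.17 for Hml, 0.34 for Hakai, -0.0102 for bol, -0.21 for Mst98Ca and -0.30 for Mst98Cb.

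Differences in peak number past the median score were -4.45% for S2 folate, 11.7% in females, 0.763% in males, 18.1% for GF-Folate, 2.02% for WT-LP and -18.0% for GF-Control against WT-Control. Over all peaks, the differences without single libraries ranged from 1.48% to 12.2% for S2 folate, -2.30% to 4.68% in females, -3.65% to 0.378% in males, 3.75% to 6.59% for GF-Folate, -0.298% to 0.543% for WT-LP and -6.52% to -4.31% for GF-Control against WT-Control. Gained and lost regions among the better-scored peaks were 274 for S2 folate, 707 in females, 657 in males, 657 for GF-Folate and 462 for WT-LP, and on same-strand exonic parts 2429 in females and 2418 in males. Fewer libraries have to agree when 1 is left out, which gave 1292 to 1998 for S2 folate, 3213 to 7295 in females, 3628 to 4654 in males, 2069 to 3018 for GF-Folate, 1993 to 2198 for WT-LP and 2419 to 3136 for GF-Control against WT-Control. The share of peaks in the last of 5 parts differed by -0.510 points between GF-Control and WT-Control among better-scored peaks.

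The correlation of female and male effects was -0.75 at 10 CPM or more, -0.18 with no filter, -0.18 with DESeq2 and -0.61 to -0.0606 without single libraries. That of GF-Folate and WT-LP effects was -0.21 with no filter and -0.39 to -0.10 without single libraries.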

Other observations

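All genes of this part belong to lists fixed before the data were examined. None of the tests here was chosen after the result was seen, apart from the median against genes of like length.

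Between GF-Control and WT-Control flies, Dcr-2, the nuclease of the antiviral small interfering RNA pathway, fell (log2 -1.27, SE 0.223, adjusted p = 0.00190, n = 3), as did AGO2, its effector (-0.61, adjusted p = 0.00550), while the cofactor gene loqs rose (0.88, adjusted p = 0.00606). The list of 10 RNA interference genes did not pass camera, and its median of -0.59 was -0.29 against genes of like length. Single genes of this part were not set against genes of like length. The eIF2alpha kinase genes Gcn2, which senses uncharged tRNA, and PEK, which senses stress of the endoplasmic reticulum, fell (-1.37, adjusted p = 0.00303, and -1.04), and crc, the fly ATF4, rose (0.62). The lipase gene Lip4 rose from 16.5 ± 3.36 to 79.8 ± 10.9 CPM (2.28, SE 0.242, adjusted p = 0.000136) and the adipokinetic hormone receptor gene AkhR by 1.15 (adjusted p = 0.00331). The basement membrane collagen genes Col4a1 (1.26, SE 0.185, adjusted p = 0.000722, from 469 ± 68.0 to 1124 ± 106 CPM) and vkg (1.07, adjusted p = 0.00295) rose together, and the dopamine synthesis gene Ddc rose from 25.3 ± 2.76 to 59.0 ± 8.33 CPM. These calls held without any one library of the 2 groups.

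Some of these genes moved the other way in GF-Folate against GF-Control flies, a comparison that shares the GF-Control libraries and so favours opposite changes even in unchanged groups. Dcr-2 rose (log2 0.89, SE 0.222, adjusted p = 0.0198), with adjusted p = 0.0868 without GF-Control 1, 0.0900 without GF-Control 3, 0.0574 without GF-Folate 2, 0.0621 without GF-Folate 3 and 0.0725 in a fit of the 2 groups alone. AGO2 rose (0.53, adjusted p = 0.0199), with 0.0867, 0.0971 and 0.0610 without GF-Control 1, GF-Control 3 and GF-Folate 2 and 0.0739 in the fit of 2 groups. Col4a1 fell (-0.74), but not past 0.05 without GF-Control 1 (0.0579), GF-Control 3 (0.0889) or GF-Folate 2 (0.0528), or in the fit of 2 groups (0.0800). The serine synthesis gene CG11899 fell from 132 ± 14.2 to 69.9 ± 4.79 CPM (-0.92, SE 0.137, adjusted p = 0.00299), and the flight muscle gene fln fell from 77.9 ± 26.8 to 34.6 ± 6.24 CPM (-1.17, adjusted p = 0.00757), both in every fit without 1 library but fln not in the fit of 2 groups (0.0627).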
